A study of Drosophila melanogaster with 6 samples.

How the data were processed

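RNA from 6 cultures of Drosophila S2 cells was hybridised to Affymetrix expression arrays, 3 cultures incubated for 1 h at 25 °C with medium alone and 3 with 25 apoptotic cell fragments per cell. Per the labels' protocols, the fragments came from S2 cells kept for 24 h in cycloheximide at 1.5 µg/ml and were collected by steps of centrifugation, the incubation took place in medium with 1% serum after maintenance in 10%, the cells were detached with trypsin and EDTA, and biotinylated cRNA was made from 150 ng of total RNA with a 3' in vitro transcription kit. Groups and replicate numbers were taken from the sample titles, which call the replicates biological without saying that a number marks a shared day.

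The deposited values were 1 log2 value per probe set and array for 18952 probe sets, between 5.35 and 14.1, with nearly equal quartiles on the 6 arrays. R 2.7.2 is named in the submitters' processing notes. The method by which the authors summarised probes and normalized arrays is not given in the sources used here, so how it treats weak or uninformative probe sets is unknown. Of the tested probe sets, 11005 (58.6%) had a range over the 6 arrays under 1e-06 and 11528 (61.4%) a range under 0.01; these are called flat. The flat probe sets had a median level of 6.23 and the others of 8.18, but a gene with a flat value is not shown to be absent. Arrays give no read depth; their number limits the precision. No scanner files were used here, and detection calls were not used here.

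The 183 control probe sets of the manufacturer were left out of the test, which left 18769. The values were used as deposited, with no level filter, no offset and no further normalization. Of the tested probe sets, 13647 had 1 gene symbol in the array annotation, 402 had several genes and were not named, and 4720 were not listed and stay unnamed. The gene identifiers of 13544 of the single-gene probe sets were found in the current RefSeq gene table (Release 6 plus ISO1 MT) and 103 were not; 0 symbols differed after the update, and the probe sets covered 11982 genes. As no genome build is named for the array values, no coordinates are given.

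The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), as fragments minus medium alone, with two-sided moderated p-values and Benjamini-Hochberg adjustment over all tested probe sets. A probe set was called at an adjusted p under 0.05. The flat probe sets drew the estimated prior variance toward 0 (prior SD 4.4e-09 log2 units, 0.123 prior degrees of freedom), so that the p-values over all probe sets were barely moderated. The fit was therefore repeated with the flat probe sets left out (7241 varying probe sets, prior SD 0.0612, 1.36 prior degrees of freedom). This choice was made after the data were seen, and both counts are given. Tested on simulated data with 50 changed probe sets per size, the fit over all 18769 probe sets recovered 38% of changes of 0.58 log2 units, 64% of changes of 1, and 88% of changes of 1.5 and of 2, with 9 false calls. With the flat probe sets left out it recovered 64%, 86%, 96% and 98%, with 10 false calls. The simulated noise was independent between probe sets and arrays, and the changes were placed in varying probe sets only. The real arrays share deviations across probe sets, so these rates and false calls do not measure the error in the real data.

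The 19 gene lists were fixed before the data were examined, as were the tests and the rule for named genes. They cover phagocytosis receptors, engulfment signalling, JNK, AP-1 and immediate early genes, Toll and Imd, JAK/STAT, heat shock, the unfolded protein and integrated stress response, apoptosis, oxidative stress and detoxification, ecdysone response, ribosomal proteins, cell cycle and DNA replication, Notch, EGFR and MAP kinase targets, actin and adhesion, lysosome and phagosome, lipid handling, central carbon metabolism, hemocyte markers and markers of other cell types. Symbols that matched no measured gene were left out, so the lists cover their pathways only in part. Of the symbols written, 9 of 24 were kept for heat shock, 19 of 31 for engulfment signalling and 15 of 22 for JAK/STAT. For apoptosis 19 of 25 were kept, and for Toll and Imd 31 of 47. The Hsp70 genes, Rac1, upd3, hid, rpr and AttA were among those lost. Each gene was represented by its probe set of highest mean, and lists of at least 5 measured members were tested with camera at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists. Camera with an estimated correlation and fry, which asks whether the members of a list move on balance 1 way without comparing them with other genes, were run beside it. Member p-values were also adjusted over each list alone. Named were the 10 largest rises and the 10 largest falls among called probe sets with 1 gene symbol whose groups did not overlap, the genes drpr, Itgbn, scb and tll, and the 3 members of smallest p in each list; where fewer than 10 had passed in a direction, the places were to be filled by smallest p among changes of at least 0.58, which was not needed.

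Alternatives planned before the data were examined were the replicate number as a block, quantile normalization, subtraction of array medians, leaving out probe sets below the median level or with a suffix that marks several transcripts, an intensity trend with and without a robust prior, an offset of 32 on the linear scale, each array left out in turn, a 1.5-fold minimum, an adjusted p under 0.10, 1 probe set per gene, no variance moderation, other probe sets of a named gene and, for lists, the mean of all probe sets of a gene. Added after the data were seen were the omission of flat probe sets, further settings on the varying probe sets, among them array weights, and scaling each array to the mean of 18 hybridisation spike probe sets. Single measures were compared with exact two-sided permutation tests, for which 3 against 3 arrays can give no p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.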

Results

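Gene expression was measured in S2 cells, a macrophage-like line derived from Drosophila embryos that engulfs particles, after incubation with fragments of apoptotic S2 cells or with medium alone. The fragments came from S2 cells that had been driven into apoptosis by the protein synthesis inhibitor cycloheximide. They were offered at 25 per cell for 1 h. Each group held 3 arrays, described in the labels as biological replicates, and the number of arrays limits the precision of every value below. The single comparison of the design, fragments against medium alone, asked which transcripts of these cultures differ after 1 h with apoptotic fragments. Any RNA or cycloheximide carried over with the fragments was absent from medium alone. Its effect cannot be told apart here from a response of the phagocytes, for rises and falls alike. The 6 arrays had median log2 values between 6.45 and 6.46 over the 18769 probe sets tested. The deposited values of 11528 of these probe sets (61.4%) moved by less than 0.01 log2 units across the 6 arrays. Larger changes are possible only in the remaining 7241, called varying probe sets here, though the main test covered all 18769.

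After 1 h with fragments, the largest changes past the threshold were falls. C1GalTA, which encodes the galactosyltransferase that builds core 1 O-glycans, went from a log2 value of 10.82 ± 0.079 (SD, n = 3) in medium alone to 9.04 ± 0.061 with fragments, a 3.43-fold fall. Tmtc3, a member of a family of O-mannosyltransferases, fell by 1.53 on the log2 scale, disp, which encodes the Hedgehog-releasing membrane protein Dispatched, by 1.59, and Brf, a subunit of the RNA polymerase III initiation factor TFIIIB, by 1.49. The largest rise past that threshold was that of Arc2, from 10.40 ± 0.088 to 11.33 ± 0.072, a 1.90-fold rise. Arc2 encodes a capsid-forming protein related to retroviral Gag. Larger rises passed only when the varying probe sets were tested alone, such as that of cbt by 1.74 log2 units (limma adjusted p = 0.00591). Zyx, the focal adhesion protein zyxin, rose by 0.62 log2 units and d4, which encodes a PHD finger protein, by 0.74.

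With limma and Benjamini-Hochberg adjustment over all 18769 probe sets, 57 probe sets of 51 genes passed an adjusted p of 0.05, 10 higher and 47 lower with fragments. Of the 47, 1 (CG12547, named after its values were seen) was a flat probe set with a change of -0.0045 log2 units. An absolute change of at least 1.5-fold was seen in 44 of the 57, with 5 higher and 39 lower, and each of the 22 that changed at least 2-fold was lower. An unadjusted p under 0.05 was reached by 2031 probe sets. When the flat probe sets were left out, a choice made after the data were seen, 496 of the 7241 varying probe sets passed, 166 higher and 330 lower (15 and 59 of them by at least 2-fold), and 54 of the 57 were among them. In 2320 varying probe sets (32%) the 3 fragment arrays lay wholly above or wholly below the 3 arrays of medium alone, against 10% by chance. Of these, 1063 were higher and 1257 lower with fragments.

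The other falls among the 10 largest were those of CG5973, CG11247, CG31908, CG17019, the UDP-glycosyltransferase gene Ugt316A1 and CG5805, with log2 fold changes between -1.51 and -1.81 and limma adjusted p between 0.00768 and 0.047. For CG5973 the change was -1.81 with an SE of 0.066, and for CG11247 -1.80 with an SE of 0.038. The other rises were smaller. CG14325 was higher by 0.78 log2 units, CG18558, which the gene table also lists as a C1GalT homologue, by 0.75 and CG12883 by 0.49. Cul6, a cullin, was higher by 0.26, CG15514 by 0.24, CG9992 by 0.11 and Ctns, the lysosomal cystine transporter cystinosin, by 0.10. The small changes of CG9992 and Ctns did not pass among the varying probe sets (adjusted p = 0.0722 and 0.0862), and the other probe set for Ctns had a log2 fold change of -0.098 that did not pass (adjusted p = 0.703). In the 20 named genes the 3 arrays of one group did not overlap those of the other, which was a condition of the naming rule.

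**Figure D1:**
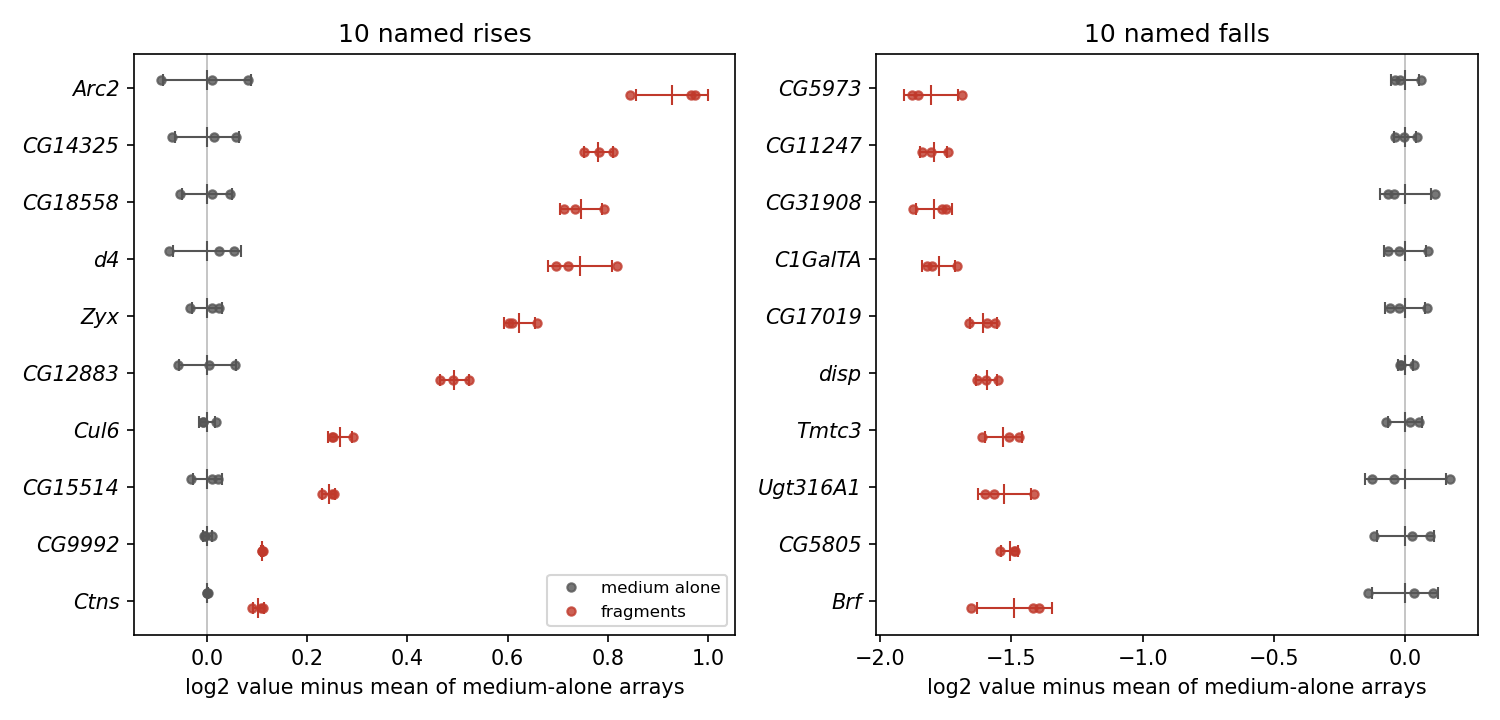
Values of the 10 named rises (left) and 10 named falls (right) on each of the 6 arrays, as the log2 value minus the mean of the 3 medium-alone arrays; points are arrays, vertical ticks are group means and bars are the SD (n = 3). The groups are apart for each gene, as the naming rule required, and the falls shown, of 1.49 to 1.81 log2 units, are larger than the rises shown, of 0.10 to 0.93. The rises are all 10 that passed over all probe sets, whereas the falls are the largest of 47. Larger rises, such as those of cbt (1.74) and Kr-h1 (1.48), passed only when the varying probe sets were tested alone and are not shown.

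The arrays of medium alone were not equally alike. Replicates 1 and 2 correlated at r = 0.9986 across probe sets, whereas replicate 3 correlated with them at r = 0.9793 and 0.9807. The fragment arrays correlated with each other at r = 0.9947 to 0.9976. Without medium-alone replicate 1, 2 or 3, limma called 156, 183 and 876 varying probe sets, and without fragment replicate 1, 2 or 3 it called 140, 129 and 318. Over all probe sets the same omissions left 0, 0, 8, 1, 0 and 8 calls, with 1656, 1639, 2056, 1470, 1432 and 1910 at an unadjusted p under 0.05. The share of falls among the calls depended on the scale: it was 82.5% as deposited, 69.5% after quantile normalization (39 higher, 89 lower) and 11.5% (1492 higher, 193 lower) when each array was set to the mean of its hybridisation spikes, bacterial and phage transcripts added to every array. That last scale, added after the data were seen, shifted every log2 fold change up by 0.26, because the spikes read 10.65 ± 0.16 in medium alone and 10.38 ± 0.11 with fragments (n = 3, exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). Every flat probe set then carried the spikes' differences between arrays and entered the variance estimate with them. Counts and p-values on this scale therefore rest in part on the spread of the spikes and are not comparable with those on the deposited values. Of the 47 falls, 44 were also lower on the spike scale, among them the 10 named falls. As the same 0.26 was added to each, this shows only that these falls exceed a shift of that size. For the 10 named falls, chosen as the largest, the outcome was fixed in advance.

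**Figure D2:**
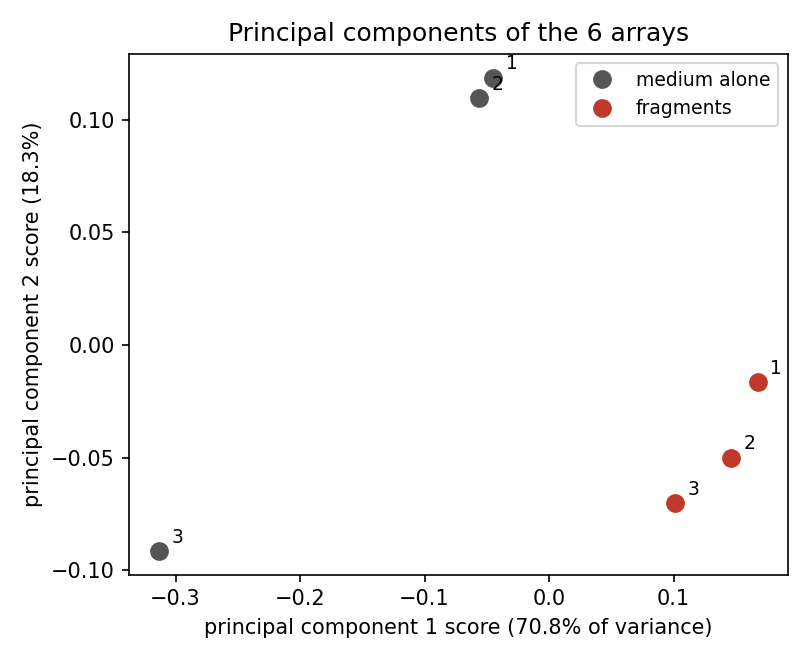
Scores of the 6 arrays on the first principal components of the varying probe sets, component 1 (70.8% of the variance) on the x axis and component 2 (18.3%) on the y axis, with replicate numbers beside the points. Medium-alone replicate 3 lies at -0.313 on component 1, against -0.045 and -0.0562 for replicates 1 and 2 and 0.10 to 0.17 for the fragment arrays.

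The receptors of apoptotic cell engulfment were examined whatever their values. The transcript of Draper (drpr), the main engulfment receptor, had a log2 fold change of -0.19 with an SE of 0.195 (limma adjusted p = 0.821), smaller than the spread of the medium-alone arrays (SD 0.341), on which replicate 3 read 8.80 and the others 9.36 and 9.42. It was -0.39 without that array (adjusted p = 0.112) and 0.068 on the spike scale, and its adjusted p ranged from 0.112 to 0.945 over the alternatives. The integrin subunit genes Itgbn and scb, whose products act together as an engulfment receptor, differed by -0.038 (SE 0.010, and 0.027 among the varying probe sets) and 0.43 (SE 0.145). Neither passed over all probe sets (adjusted p = 0.342 and 0.421) or adjusted over the 4 genes of this paragraph alone (0.0768 for both), or over the list of phagocytosis receptors alone (0.171 and 0.192). On the spike scale scb was higher by 0.70 and passed (limma adjusted p = 2.17e-05), but that p-value rests in part on the spread of the spikes. Over the alternative settings the adjusted p of scb ranged from 2.17e-05, on the spike scale, to 0.756. The transcription factor gene tailless (tll) read 6.104 on each of the 6 arrays, a flat value that can show no change. On the spike scale even tll had a difference of 0.26, with a limma adjusted p of 0.0737.

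Phagocytosis receptors did not pass as a group. Of 25 measured members, 14 of them flat, 0 passed over all probe sets and 1 fell when adjusted over the list alone (limma). The competitive gene set test camera gave an adjusted p of 0.966. An unadjusted limma p under 0.05 was reached by crq, pes, Itgbn, Sr-CII and scb, and by 2031 of the 18769 probe sets of the whole array. Of these, Itgbn and Sr-CII differed by only -0.038 and 0.0061 and read 6.15 and 5.76 in medium alone, below the median of the flat probe sets (6.23). Among the varying probe sets their unadjusted limma p was 0.21 and 0.819. The member that fell was crq, which encodes the CD36-family receptor Croquemort, from 10.10 ± 0.085 to 9.30 ± 0.10 (log2 fold change -0.80, adjusted p = 0.0698 over all probe sets and 0.00559 among the varying ones). A second CD36-family gene, pes, differed by 0.45 and did not pass over all probe sets (adjusted p = 0.301), but with the flat probe sets left out it passed adjusted over the list alone (0.0301). Among 19 engulfment signalling genes (camera adjusted p = 0.354), Fak, the focal adhesion kinase, fell and Pvf2, a PDGF- and VEGF-related ligand, rose when adjusted over the list alone, with log2 fold changes of -0.83 and 0.31. Ced-12, a Rac activator of the engulfment pathway, differed by 0.15 and did not pass (adjusted p = 0.344).

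Genes of JNK and AP-1 signalling and the immediate early response passed upward as a list with camera at its preset correlation, but not with an estimated correlation or with fry. That preset setting called at least 2 lists in 6 of the 10 splits of the arrays into 3 and 3, the real split included. The 22 measured members had a median log2 fold change of 0.20 (camera adjusted p = 0.0124 with the preset correlation, but adjusted p = 0.751 with an estimated correlation and 0.503 with fry). Over all probe sets 0 members passed in limma, and adjusted over the list alone 3 rose and 1 fell. These were cbt, a zinc finger transcription factor gene, higher by 1.74 log2 units or 3.33-fold, the MAP kinase phosphatase gene Mkp3, higher by 0.58, kay, the Drosophila Fos, higher by 0.56, and wgn, a TNF receptor gene, lower by 0.65. The gene kay lies outside the naming rule and was added after its values were seen. With the flat probe sets left out, 6 members rose and 2 fell adjusted over the list alone. The highest members also read low on medium-alone replicate 3: cbt stood at 9.98 there, against 10.55 and 10.40 on the other 2 arrays of medium alone and 11.95 to 12.11 on the fragment arrays. Over all probe sets, the call of the list ended without medium-alone replicate 3 (camera adjusted p = 0.0715) and without fragment replicate 1 (0.0655). Among the varying probe sets its camera adjusted p was 0.00144, and 0.000615 to 0.00919 with 1 array left out. With an estimated correlation it was 0.848 there. Over the alternatives on all probe sets, the adjusted p of the list ranged from 2.00e-08, on the spike scale, to 0.751.

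The list of cell cycle and DNA replication genes passed downward with camera at its preset correlation, but not with an estimated correlation or with fry. The 30 measured members had a median log2 fold change of -0.16 on the deposited scale, which became 0.098 on the spike scale (camera adjusted p = 8.57e-05 with the preset correlation, but adjusted p = 0.751 with an estimated correlation and 0.0981 with fry). Over all probe sets 1 member passed, Cdc6, which loads the replicative helicase at origins; it fell from 8.38 ± 0.050 to 7.48 ± 0.098, a 1.86-fold change (limma adjusted p = 0.047). Adjusted over the list alone, 10 members fell and 2 rose. Among the falls were CycB3, a mitotic cyclin, with a log2 fold change of -0.77 and, added after their values were seen, the S-phase cyclin CycE with -0.67 and its partner kinase Cdk2 with -0.60. The subunit of the origin recognition complex Orc1 went the other way, by 0.48. The adjusted p of the list ranged from 2.30e-05, on the spike scale, to 0.751 over the alternatives.

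**Figure D3:**
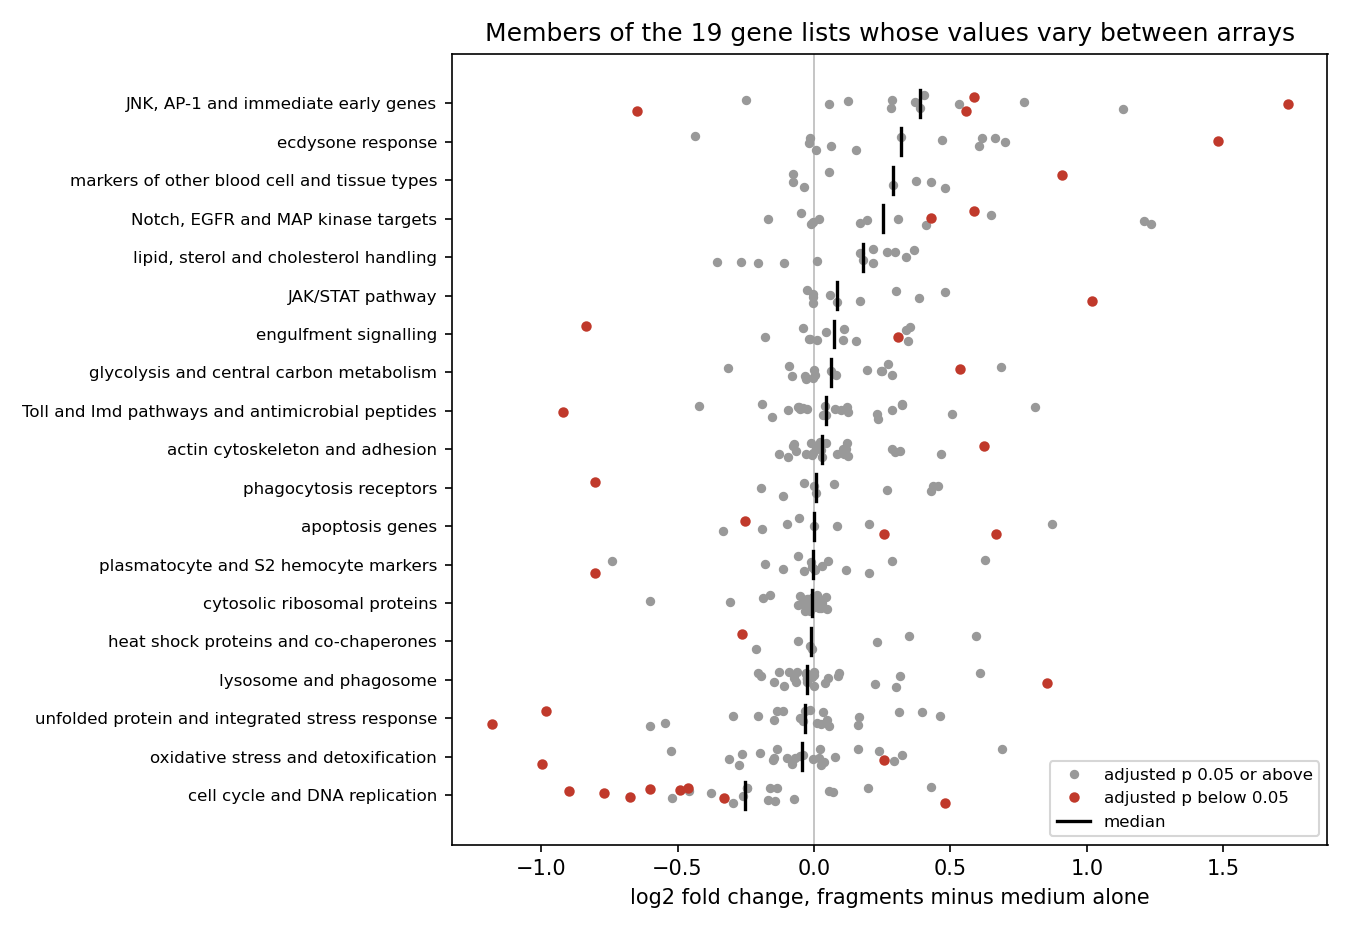
Log2 fold change (x axis, fragments minus medium alone) of the members of each of the 19 gene lists whose values varied between arrays; each point is 1 gene, red points passed an adjusted p of 0.05 among the varying probe sets, and black bars are medians. Members of the cell cycle list lie mostly below 0 and those of the JNK and AP-1 list mostly above it on the deposited scale; on the spike scale every point moves up by 0.26, and 11 of the 24 cell cycle members then lie below 0 instead of 19.

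Ecdysone response genes and targets of Notch, EGFR and MAP kinase did not pass over all probe sets (camera adjusted p = 0.0768 and 0.0918). With the flat probe sets left out both lists passed, upward, at 0.0345 and 0.0298, but with an estimated correlation their adjusted p was 0.848 there. Over the alternatives on all probe sets, their adjusted p ranged from 1.43e-05 to 0.751 and from 3.3e-06 to 0.751, both lowest on the spike scale. Kr-h1, an ecdysone- and juvenile hormone-responsive transcription factor gene, rose from 7.69 ± 0.30 to 9.17 ± 0.12 (adjusted p = 0.0102 among the varying probe sets) and was the only 1 of the 20 measured ecdysone genes to pass adjusted over the list alone. EcR, the ecdysone receptor gene, and MsrA differed by 0.47 and -0.44 and did not pass. Of 20 measured Notch, EGFR and MAP kinase targets, 2 rose and 1 fell adjusted over the list alone. The rises were those of Mkp3 and of sty, which encodes Sprouty, a feedback inhibitor of receptor tyrosine kinases, by 0.43 log2 units, and the EGFR ligand gene spi fell by 0.17, a fall smaller than the 0.26 that the spike scale adds. Among the varying probe sets the call of both lists ended without fragment replicate 1 (adjusted p = 0.119 and 0.0867), and that of the ecdysone list also without fragment replicate 2 (0.0505). Without medium-alone replicate 3, on which Kr-h1 stood at 7.34 against 7.87 and 7.84 on the other arrays of medium alone, both still passed (0.0308 and 0.0291).

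The lists of stress and death genes did not pass with camera on the deposited values of all probe sets. In the unfolded protein and integrated stress response list (25 measured members, camera adjusted p = 0.295, but 0.0134, downward, with probe sets of ambiguous suffix left out; 0.0134 to 0.885 over the alternatives), 2 genes fell adjusted over the list alone, both eIF2-alpha kinases. Gcn2, which senses uncharged tRNA, went from 8.51 ± 0.12 to 7.33 ± 0.13, a 2.27-fold fall (limma adjusted p = 0.0613 over all probe sets and 0.00393 among the varying ones), and PEK, the kinase of the endoplasmic reticulum, had a log2 fold change of -0.98 (0.164 and 0.0193). GstD1 differed by -0.14 and did not pass. Of 19 apoptosis genes (camera adjusted p = 0.804), the initiator caspase gene Dronc and the caspase gene Strica rose, by 0.26 and 0.67 log2 units, and scu, a mitochondrial dehydrogenase gene, fell by 0.25, adjusted over the list alone. On the spike scale, which adds 0.26, the difference of scu was close to 0. With the flat probe sets left out, 3 apoptosis genes rose and 3 fell adjusted over the list alone (limma). They included dnr1, higher by 0.87, and AIF and Dredd, lower by 0.34 and 0.19, the last a fall smaller than that 0.26. The genes dnr1, AIF and Dredd were added after their values were seen. Among 36 oxidative stress and detoxification genes (camera adjusted p = 0.633) the glutathione transferase gene GstD3 fell by 1.00 adjusted over the list alone, while GstD10 and Prx3, with differences of 0.26 and -0.15, did not pass there; among the varying probe sets GstD10 passed (adjusted p = 0.0389). The 9 measured heat shock genes, with no Hsp70 gene among them (camera adjusted p = 0.882), had 0 members past the threshold adjusted over the list alone in limma. Of these, Hsp60A differed by -0.26 (adjusted p = 0.0472 among the varying probe sets, and close to 0 on the spike scale), Hsf, the heat shock factor gene, by 0.35 and the co-chaperone gene stv by 0.59.

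The lists of immune pathway genes did not pass with camera on the deposited values. Of 31 Toll and Imd genes (camera adjusted p = 0.633) and 15 JAK/STAT genes (0.315), 0 passed in limma over all probe sets or adjusted over the list alone. Both lists passed upward after quantile normalization (0.0333 and 0.0123), and that of JAK/STAT also with array medians subtracted (0.0146) and on the spike scale (0.00964), but with an estimated correlation the adjusted p of both was 0.793. Over the alternatives it ranged from 0.0333 to 0.931 and from 0.00964 to 0.793. The antifungal peptide gene Drs had a log2 fold change of -0.92 with an SE of 0.201 (adjusted p = 0.257 over all probe sets, 0.0456 among the varying ones), and the adaptor genes tub and imd differed by -0.42 and 0.24. Of the JAK/STAT genes, ken, a transcriptional repressor gene, was higher by 1.02 log2 units (adjusted p = 0.211 and 0.0309), with medium-alone replicate 3 at 8.63 and the other arrays of medium alone at 9.16 and 9.21. The receptor gene dome and the phosphatase gene Ptp61F differed by 0.48 and 0.30 and did not pass over all probe sets; with the flat probe sets left out dome passed adjusted over the list alone (0.0465). Of 20 markers of plasmatocytes and S2 cells, 1 fell adjusted over the list alone, crq (camera adjusted p = 0.589); Ppn and eater differed by -0.74 and -0.11 and did not pass over all probe sets, but with the flat probe sets left out Ppn passed adjusted over the list alone (0.0373). Markers of other blood cell and tissue types, 26 measured and 17 of them flat, did not pass as a group (camera adjusted p = 0.199), with 0 members past the threshold adjusted over the list alone in limma. Of these bam, a germline differentiation gene, was higher by 0.91 (adjusted p = 0.181 over all probe sets and 0.0224 among the varying ones), and dome and peb differed by 0.48 and 0.38 (0.0381 and 0.0553 adjusted over this list alone with the flat probe sets left out).

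The lists on structure and metabolism did not pass with camera on the deposited values. Zyx was the 1 member of 33 in the actin and adhesion list that passed (camera adjusted p = 0.199). The list passed upward with array medians subtracted (0.0146) and without medium-alone replicate 1 (0.0332) or 2 (0.0468), and its adjusted p ranged from 0.0146 to 0.793 over the alternatives. In it cpa and Arpc2, subunits of capping protein and the Arp2/3 complex, differed by 0.31 and -0.095. Of 38 lysosome and phagosome genes (camera adjusted p = 0.633), Mitf, a transcription factor gene of lysosomal programmes, rose from 6.82 ± 0.10 to 7.67 ± 0.064 adjusted over the list alone (limma adjusted p = 0.0553 over all probe sets and 0.00367 among the varying ones). Vha36-1, a proton pump subunit gene, and Atg18a, an autophagy gene, differed by -0.11 and 0.30 and did not pass. The lists of lipid and sterol handling (27 members), glycolysis and central carbon metabolism (21) and cytosolic ribosomal proteins (41) had camera adjusted p of 0.252, 0.295 and 0.589, and 0 of their members passed adjusted over the list alone in limma. The glycolysis list passed upward after quantile normalization (0.0333) and with array medians subtracted (0.0477), and the ribosomal list downward with probe sets of ambiguous suffix left out (0.0456); their adjusted p ranged from 0.0333 to 0.907 and from 0.0456 to 0.805. With the flat probe sets left out, 5 genes of the lipid list passed adjusted over that list alone (0.0386 each), with Abca3, Hnf4 and bmm higher and SREBP and Lsd-1 lower (on the spike scale the difference of SREBP was close to 0); Hnf4, bmm and Lsd-1 were added after their values were seen. In these lists SREBP and Abca3 differed by -0.27 and 0.30, the sugar-responsive transcription factor gene sug by 0.53 (0.0272 among the varying probe sets), Hex-A by 0.68 and Tpi by -0.034, and RpL7-like and RpL24-like by -0.16 and -0.31. Lsd-2 in the lipid list and RpS28a in the ribosomal list, also among the 3 members of smallest p, were flat.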

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

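The alternatives on varying probe sets and on the spike scale, and the omission of flat probe sets, were chosen after seeing the data; the others were planned. Of 1705 values recomputed under alternatives, 1376 stayed on their side of the threshold or within 1.5 times a count (44 of them with a change of sign between values that passed in neither setting), 59 counts moved further, 169 values no longer passed, 100 newly passed and 1 reversed, the other probe set of Ctns (-0.098 against 0.10), which did not pass. The cause was not tested except where fewer probe sets or arrays give it.

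Against 10 probe sets higher and 47 lower, the counts were 39 and 89 after quantile normalization, 33 and 105 with array medians subtracted, 47 and 158 without dim probe sets, 2 and 17 without probe sets of ambiguous suffix, 35 and 99 at an adjusted p under 0.10, 1492 and 193 on the spike scale and 166 and 330 without flat probe sets. The count of higher probe sets was 17 with an intensity trend, 5 at a minimum of 1.5-fold and 20 with 1 probe set per gene. Leaving out 1 array, which leaves 3 residual degrees of freedom, gave 0 to 2 higher and 0 to 7 lower. Without variance moderation 60 probe sets passed, 14 of them with changes under 0.01 log2 units. Among varying probe sets, 643 higher and 939 lower passed with array weights, 1322 and 168 on the spike scale, and 29 to 342 and 100 to 534 with 1 array left out; without medium-alone replicate 3, 476 of the 496 calls were still made.

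With the replicate number as a block, limma called 0 higher and 0 lower over all probe sets, with 1868 at an unadjusted p under 0.05, and 131 higher and 318 lower among varying probe sets. Arrays with the same number deviated together at r = 0.442, 0.038 and 0.375, so the numbers are not shown to pair the cultures, and not every array correlated best with its own number.

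Against 2 gene lists called, 7 were called after quantile normalization and with array medians subtracted, 4 without dim probe sets and without flat probe sets, 1 with either intensity trend, 5 on the spike scale and 1 to 4 with 1 array left out. With camera's estimated correlation 0 were called, and 0 of the 19 lists had an unadjusted p under 0.05; with fry 0 were called and 1 had, against 14 by its mixed p, which disregards direction. The adjusted p of the JNK and AP-1 list was 0.144 without probe sets of ambiguous suffix, 0.0879 with either intensity trend, 0.751 with an estimated correlation, 0.503 with fry and 0.00313 to 0.0715 with 1 array left out. That of the cell cycle list was 0.751 with an estimated correlation and 0.0981 with fry and stayed under 0.05 in the other alternatives. The log2 fold change of scb, 0.43 as deposited, was 0.70 on the spike scale, where it passed with a p-value that rests in part on the spread of the spikes.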

Other observations

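The lists, genes and tests in this part were chosen after the values were seen, except the counts over splits of the arrays. Genes of glycan assembly and Golgi glycosylation, gathered by gene family name without regard to sign, were mostly lower on the deposited scale. Of 88 members with varying values, 69 were lower and 19 higher with fragments, against 53.6% lower among varying genes; on the spike scale, which adds 0.26 to each, 29 were lower. Camera gave p = 4.6e-08 at the preset correlation, but p = 0.0873 with an estimated correlation of 0.116, and fry gave p = 0.00072; as the list was written after its members had been seen, these p-values are not independent evidence. Among the varying probe sets 22 fell and 2 rose (limma). The falls spanned O-glycan synthesis (C1GalTA), N-glycan branching in the Golgi (Mgat1, log2 fold change -1.36; Mgat4a, -1.27), dolichol phosphate synthesis (Dolk, -1.14), GPI anchor synthesis (PIG-O, -1.26) and transport of the sulfate donor into the Golgi (sll, -1.38; Papst2, -1.23). The rises were those of CG18558 and Xxylt.

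Of 11 measured circadian clock genes, the 6 with varying values had a median log2 fold change of 0.77 on the deposited scale, and of 0.56 without medium-alone replicate 3. Of these cbt passed, whereas cwo (1.12, adjusted p = 0.0793 among the varying probe sets), vri (1.07, 0.0929), Pdp1 (0.48, 0.103), cyc (0.028, 0.634) and dco (0.048, 0.777) did not; in cyc and dco the 2 groups overlapped. Camera gave p = 0.00071 for this list and p = 0.144 with an estimated correlation. As this list was also chosen after the values were seen, these p-values are not independent evidence, and cbt is a member of the JNK and AP-1 list as well. The largest fall among the calls in the varying probe sets was that of zpg, a germline innexin gene (-1.97, SE 0.231), which did not pass over all probe sets. Also past the threshold among the varying probe sets were daw, which encodes an activin-like ligand (1.25), Drat (1.47) and the spindle midzone gene feo (-1.22).

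The fall of the glycan genes was set against the scale of the arrays, 1 unusual array and carried-in RNA. On the spike scale the median of the 88 members turned from -0.097 to 0.165, as a shift of 0.26 in every gene must make it do, so a fall of the list as a whole cannot be told apart from an effect of scale. Of the 22 falls that had passed, 21 were lower on the spike scale and 15 were still called lower. As the same 0.26 was added to each, this shows only that these falls exceed a shift of that size. It is no test of their cause. Without medium-alone replicate 3 the median was -0.0953, which argues against that array as the source. RNA from the fragments cannot be told apart from regulation, since the RNA of fragments alone was not analysed here; to give the largest fall by dilution, 70.8% of the RNA would have to be carried-in RNA without that transcript.

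Falls outnumbered rises among the calls. Scaled to the spikes, 11.3% of the called varying probe sets were lower, against 66.5% as deposited. As that scale adds 0.26 to every log2 fold change, the turn follows from its construction, and the excess of falls cannot be told apart from an effect of the authors' normalization. Without medium-alone replicate 3, 61.0% were lower, which argues against that array as the whole cause. With any other array left out the share was higher, 74.3% to 78.2%, so a part played by that array is not excluded. Which scale is right stays open, as the spikes differed between groups by -0.262 log2 units (exact two-sided permutation p = 0.2, n = 3). The spikes were added to the arrays and not to the cells, so their scale is no measure of RNA content per cell.

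In part, and mainly for the rises, medium-alone replicate 3 deviated from its 2 replicates in the direction opposite to the fragment response. Of the 876 varying probe sets called without that array, 62.6% deviated opposite to the change with fragments. Among them 251 of 342 rises were lower there (median -0.223) and 297 of 534 falls higher (median 0.046). The share was 52.7% over all varying probe sets, and 48.8% was expected from the shares of rises and falls alone. In 2 further versions the deviation was taken from 1 of the other 2 arrays of medium alone and the change from the second. The share among the calls was then 62.7% and 63.9%, against 56.4% and 55.2% over all varying probe sets. Across all varying probe sets the correlation was weak, -0.214, and a hypothesis is that part of the fragment response, the rises in particular, lies along a culture or handling state, such as the response to medium change or detachment, which may also vary between untreated cultures. Loss of 5' signal in that RNA sample is argued against. In 0 of 3 transcripts (GAPDH, actin and eIF4a) did the difference between 3' and 5' probe sets on that array lie above the other 5 arrays. That array did have the highest spike mean, 10.785 against 10.271 to 10.68 on the others. Its 18S rRNA probe set read lowest, 12.366 against 12.493 to 12.763. Another technical difference of that array is therefore not excluded. With 1 such array and no record in the labels of how each single culture was handled, the state itself was not tested.

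The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 57 calls over all probe sets and 496 among the varying ones, and the highest of the others 0 in both cases, so 1 of the 10 splits gave as many. For gene lists, 6 of the 10 splits gave at least the 2 lists of the real split, the highest of the others giving 5.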
